A study of Mus musculus with 1600 samples.

How the data were processed

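The series measured RNA in single wells of the Fluidigm C1 system, a microfluidic chip that captures cells in separate chambers, for glomerular cells of mice that lack endothelial nitric oxide synthase (the gene Nos3). Per the labels and the design text, mice received streptozotocin, a toxin of the insulin-producing beta cells, at 50 µg per g body weight on each of 5 days from the age of 8 weeks, or citrate buffer. Glomeruli were taken at 10 weeks after perfusion with magnetic beads and digested to single cells with collagenase, Pronase and DNase. Cells of 3 mice were pooled per condition, and the whole was done in 2 experiments, so there were 4 pools: 2 of control mice and 2 of diabetic mice. By the column and row of each well in the labels, the 800 wells of an experiment filled 1 array that held both conditions, with 400 wells per pool. The labels also give the number of cells seen in each well by imaging, which was 0 in 588 wells, 1 in 833, 2 in 98, and more than 2 or debris in 81.

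The deposited gene tables, one per experiment, hold expected counts, that is, reads per gene and well that need not be whole numbers. Among the values above 0, 74.1% were whole in experiment 1 and 79.3% in experiment 2, and the rest were fractions such as 0.5 or 0.33. Per the submitters' processing notes, the authors used cutadapt 1.11, STAR 2.4.2a, BWA 0.7.17-r1188 and featureCounts 1.5.1 with the mouse build mm10, and the role and order of the tools and the annotation release are not given in the sources used here. How reads that fit several genes were split is likewise not given, so values of genes with near-identical copies are uncertain, such as those of the ribosomal protein, haemoglobin, immunoglobulin and histocompatibility families. Whether strand was used is not given either, so genes that overlap on opposite strands cannot be told apart. The deposited spike-in table, for experiment 1 alone, holds counts of reads on 95 spike-in sequences per well, and 96.3% of these reads fell on 1 of them. No molecular identifiers were counted, so reads are not independent molecules. All binomial intervals are on numbers of wells and cover counting error only, since the wells of a pool are not replicates of a condition.

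Genes were named through GENCODE M21 (GRCm38), which also gave coordinates. Of 45792 gene identifiers, 45229 matched without their version and 563 did not. Wells were used if exactly 1 cell had been imaged, at least 500 genes had 1 count or more, and genes of the mitochondrial genome took at most 30% of the reads. Of 189 and 218 single-cell wells of control replicates 1 and 2, 120 and 203 were kept; of 188 and 238 wells of diabetes replicates 1 and 2, 128 and 188 were kept, 639 in all. No doublet caller was run, since imaging gave the number of cells. Depth differed by experiment: the kept wells of control replicates 1 and 2 had a median of 32222 and 219072 reads, and those of diabetes replicates 1 and 2 a median of 43577 and 176715.

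Values were scaled to log2(counts per 10000 + 1). The 2000 most variable genes were centred and scaled within each experiment, and 15 principal components, 15 neighbours and Leiden clustering at resolution 0.8 gave the clusters (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). A cluster was called after a cell type if at least 3 of that type's markers were detected in 25% of its wells, if that type had more markers than any other among the 50 leading genes by fold, and if at least 1 stood among the top 10. The markers were chosen before the data were examined, as were the tests, the filters, the 22 gene lists and 8 marker lists, the rule for named genes and all alternatives not said to be added; the limits of 25%, 50 and 10 in the naming of clusters were set with the data at hand. Shares of classes among kept wells were given with exact Clopper-Pearson 95% intervals per pool. With 2 pools against 2, an exact two-sided permutation test cannot give a p under 0.333, so shares were not tested across pools.

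For gene comparisons, cells were not treated as replicates. The expected counts of a class's wells were summed per pool, rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling, filterByExpr by condition), with the experiment as a block, which leaves 1 residual degree of freedom per gene before the spread is shared across genes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The weight of the shared spread, in prior degrees of freedom of the median gene, was 5.95 in endothelial-like sums. It was infinite in the mesangial-like, immune-like and podocyte-like fits, where a typical gene's own spread between pools did not enter its p. Numbers of calls and sizes of p are therefore not comparable between endothelial-like sums and these fits. A class was tested if every pool held at least 5 of its wells; podocyte-like wells did not reach this (2 wells in diabetes replicate 1), so that test and the 2 tests of podocyte-like against other classes were not run as planned. Podocyte-like sums were fitted instead without that pool and without the block, a choice made after seeing the data. The difference between the responses of 2 classes was tested as a class-by-condition term with the pool as a block. The SE given with an edgeR fold change is its absolute size divided by the square root of its F statistic. It is not comparable between classes, whose F statistics have different degrees of freedom. Fold changes are log2 of diabetes over control, CPM stands for counts of the summed wells over their TMM-scaled library size, as edgeR gives them, unless said otherwise, and n = 2 pools per condition with 3 exceptions (the podocyte-like fit of 3 pools, the fits leaving out a pool and the spike-in ratios have 1 pool in a condition).

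Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01) on the same design, adjusted over 84 tests of lists in classes. Camera with an estimated correlation and fry were alternatives. Both rest on the 1 residual degree of freedom of this design and could hardly pass after adjustment. A list that fails them is therefore neither upheld nor refuted, and the list results rest on the preset correlation. Genes were named by this rule: in each class, among genes past the threshold whose CPM moved the same way in both experiments, the 10 largest rises and 10 largest falls, with up to 2 called members of each list. If fewer than 10 genes passed, the 10 with the smallest p that moved the same way in both experiments were given as values. Nos3 and up to 4 members of each list that passed were given as values. Predicted gene models and pseudogenes were counted and not named, and a gene with over 80% of a pool's counts from 1 well is named with that said. Genes named outside the rule are marked as chosen after their values were seen.

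The experiment number in the labels was used as the block, since both conditions of an experiment lay on 1 array: the correlation of same-numbered pools' deviations from the condition means was 0.13 in endothelial-like, 0.10 in mesangial-like and 0.12 in immune-like sums. Alternatives were DESeq2 1.42.0, other scalings, other filters on genes and wells, wells thinned to 10000 reads, limma on mean log values, classes by the highest marker share, sums without mixed wells, fits without the block and fits leaving out each pool. The fits leaving out a pool were also made without the block. Added after seeing the data were the subtraction of the profile of wells imaged empty, the removal of genes on chromosomes X and Y, the removal of wells rich in immunoglobulin reads, and shares without any filter on wells. Figures were drawn with matplotlib 3.10.9.

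The tests were tried on simulated counts with the real means and library sizes and 200 genes changed, 100 by 2 and 100 by 6 on the log2 scale. With the estimated spread (a biological coefficient of variation of 0.76 in endothelial-like, 0.97 in mesangial-like and 1.10 in immune-like sums), no change of 2 was called in any of these classes, and a change of 6 was called for 54% of genes in endothelial-like sums and for 0% in the other classes and in the difference between endothelial-like and mesangial-like. With a small spread (dispersion 0.02), 98%, 98%, 84% and 70% of changes of 2 and 100%, 100%, 100% and 95% of changes of 6 were called, in that order. The larger change and the small spread were added after a first simulation with changes of 1 and 2 recovered none. All genes of a class were simulated with the same spread, whatever their level. The real mesangial-like fit called genes with changes of under 2, such as Adamts5 and Sfrp2, which the simulation with the estimated spread did not recover. The simulation therefore does not give the power for single genes in these pools, and a low count of calls does not show that few genes changed.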

Results

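Single glomerular cells were profiled from mice without endothelial nitric oxide synthase. The question set by the design was how each glomerular cell type differs between mice made diabetic with streptozotocin and control mice given citrate, at 10 weeks of age and 2 weeks after the first injection. Each of 2 experiments held 1 pool of 3 control mice and 1 pool of 3 diabetic mice. After filtering, 639 single-cell wells remained: 120 and 203 of control replicates 1 and 2, and 128 and 188 of diabetes replicates 1 and 2. Their total reads on genes were 4.76e+06, 4.84e+07, 6.72e+06 and 3.80e+07 in the same order, and the median number of genes detected per well was 2094, 3674, 2578 and 3793. After thinning to 10000 reads per well these medians were 1671, 1599, 1866 and 1691, with 13 and 14 shallower wells of control replicate 1 and diabetes replicate 1 left out.

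Wells in which no cell was seen also held RNA. In experiment 1 the median was 624 genes in empty control wells and 831 in empty diabetes wells, against 1549 and 2141 in wells with 1 cell and 2590 and 2979 in wells with 2 cells. In experiment 2, empty wells had a median of 3857 genes in control and 3216 in diabetes, close to the 3609 and 3503 of wells with 1 cell. Their median reads were 33610 against 216648 in control and 32994 against 152913 in diabetes. Counting only genes with at least 2 counts, wells with 1 cell of experiment 1 had a median of 1096 genes in control and 1602 in diabetes. Empty wells had 185 and 249.5. In experiment 2 the medians were 2580.5 and 2626 against 2428 and 2075, so control wells with 1 cell barely exceeded empty ones. The ratio to empty wells, as a mean of control and diabetes, was 6.17 in experiment 1 and 1.16 in experiment 2. In experiment 1, spike-in reads took 84.5% (control) and 81.3% (diabetes) of the reads of the median empty well and 23.8% and 19.7% of those of the median single-cell well. Median reads on genes per spike-in read were 3.74 in 48 control and 4.22 in 71 diabetes endothelial-like wells, with overlapping quartiles (2.21 to 4.71 and 2.94 to 5.80). They were 3.53 in 5 control and 7.63 in 28 diabetes immune-like wells. These are values of 1 pool per condition, without a replicate.

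The 9 clusters of kept wells fell into endothelial-like (295 wells in 3 clusters), mesangial-like (125), immune-like (79), podocyte-like (76), tubular-like (24) and smooth muscle or renin cell-like (20) classes, and 20 wells led by Mgp, Col1a2 and Dcn stayed unnamed. The diabetes pools held more immune-like and fewer mesangial-like wells than the control pools in both experiments. Immune-like wells, led by Lyz2 (lysozyme of myeloid cells), Fcer1g and the class II gene H2-Ab1, made up 4.17% (95% exact interval 1.37 to 9.46) and 2.46% (0.804 to 5.65) of control wells and 21.9% (15.1 to 30) and 21.8% (16.1 to 28.4) of diabetes wells. Mesangial-like wells, the contractile pericytes of the glomerulus, were 24.2% (16.8 to 32.8) and 33.5% (27.0 to 40.4) in control against 3.91% (1.28 to 8.88) and 12.2% (7.92 to 17.8) in diabetes. Podocyte-like wells, the filtering epithelium, were 20% (13.3 to 28.3) and 15.3% (10.6 to 21) against 1.56% (0.190 to 5.53) and 10.1% (6.20 to 15.3), and their intervals overlapped in experiment 2. Endothelial-like wells were 40.0% (31.2 to 49.3) and 40.9% (34.1 to 48.0) against 55.5% (46.4 to 64.3) and 49.5% (42.1 to 56.8), with overlapping intervals in both experiments.

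Shares of one total cannot move independently, and these differences are given as values within each experiment, without a test across pools. An exact permutation test of 2 pools against 2 gives no p under 0.333. In experiments 1 and 2 the differences were 17.7 and 19.3 percentage points for immune-like, -20.3 and -21.3 for mesangial-like, -18.4 and -5.16 for podocyte-like and 15.5 and 8.58 for endothelial-like wells. Their means were 18.5, -20.8, -11.8 and 12. Digestion, capture and the mitochondrial filter can set such shares: that filter left out 33.9% and 6.88% of the single-cell wells of control replicates 1 and 2 and 30.9% and 21% of diabetes replicates 1 and 2. With no filter on wells the endothelial-like difference was 12.4 in experiment 1 and -0.112 in experiment 2, a mean of 6.15, and the mesangial-like differences were -10.6 and -20.5. With mitochondrial reads at most 15% of a well, 13 of the 41 immune-like wells of diabetes replicate 2 remained (12% of its wells), and the immune-like differences were 19.6 and 10.1. At a finer clustering (resolution 1.2), immune-like wells were 3.33% and 1.48% in control against 16.4% and 7.98% in diabetes, a mean difference of 9.79. In that clustering 27 wells of diabetes replicate 2 went unnamed. The 2 podocyte-like wells of diabetes replicate 1 (1.56%) became 10 (7.81%) in it, and 11 (5.85%) with no filter on wells. In diabetes replicate 2, 10 of 41 immune-like wells held an immune marker share above the 95th percentile of the empty wells of the same pool, against 22 of 28 in diabetes replicate 1. Ptprc, the pan-leukocyte gene Cd45, had reads in 75.6% and 89.3% of them.

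**Figure D1:**
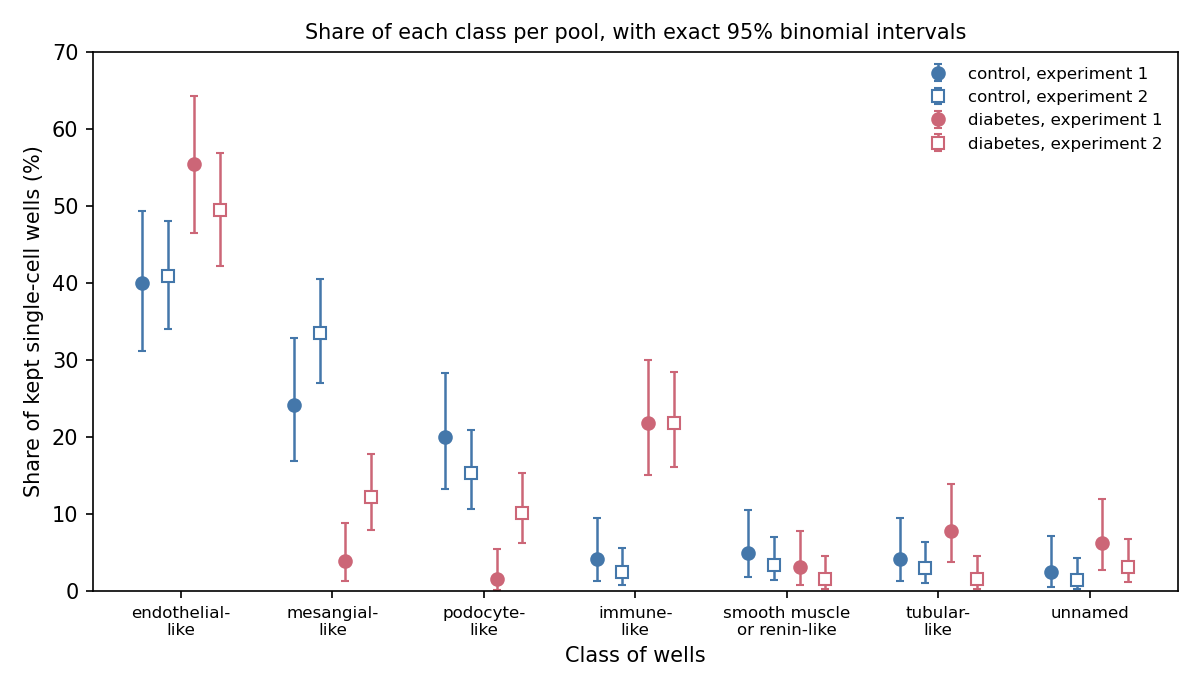
Share of each class among kept single-cell wells (percent, vertical axis) for the 4 pools, with bars for exact 95% binomial intervals that cover counting error only. Immune-like wells stand at 21.9% and 21.8% in the diabetes pools against 4.17% and 2.46% in the control pools, and mesangial-like wells at 3.91% and 12.2% against 24.2% and 33.5%.

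Sex-linked transcripts separated the pools by condition. Xist, the RNA that silences one X chromosome in female cells (ENSMUSG00000086503.3, chromosome X, 103460366 to 103483254, GRCm38), stood at 356 and 442 CPM (not TMM-scaled) in kept wells of the control pools and at 1.42 and 1.40 in the diabetes pools. The Y-linked genes Ddx3y (chromosome Y, 1260771 to 1286629), Eif2s3y (1010543 to 1028847), Kdm5d (897788 to 956786) and Uty (1096861 to 1245759) together had 0.279 and 0.605 CPM in control and 154 and 160 in diabetes. Of the kept wells, 81 and 173 of the control pools had Xist reads without reads of the 4 Y-linked genes, and 0 and 1 had the reverse. In the diabetes pools, 4 and 3 had Xist alone and 69 and 148 had Y-linked reads alone. Kdm6a, an X-linked gene that escapes inactivation, was 2.49 and 3.02 times as high in control as in diabetes, and Eif2s3x 2.56 and 2.32 times. Of 2 further such genes, Ddx3x was 1.67 and 1.79 times as high, and Kdm5c 0.923 times in experiment 1 and 2.06 times in experiment 2. The design text describes sex-matched littermates. In these pools condition and sex-linked expression went together in both experiments. No comparison of diabetes with control in these data can be separated from them.

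**Figure D2:**
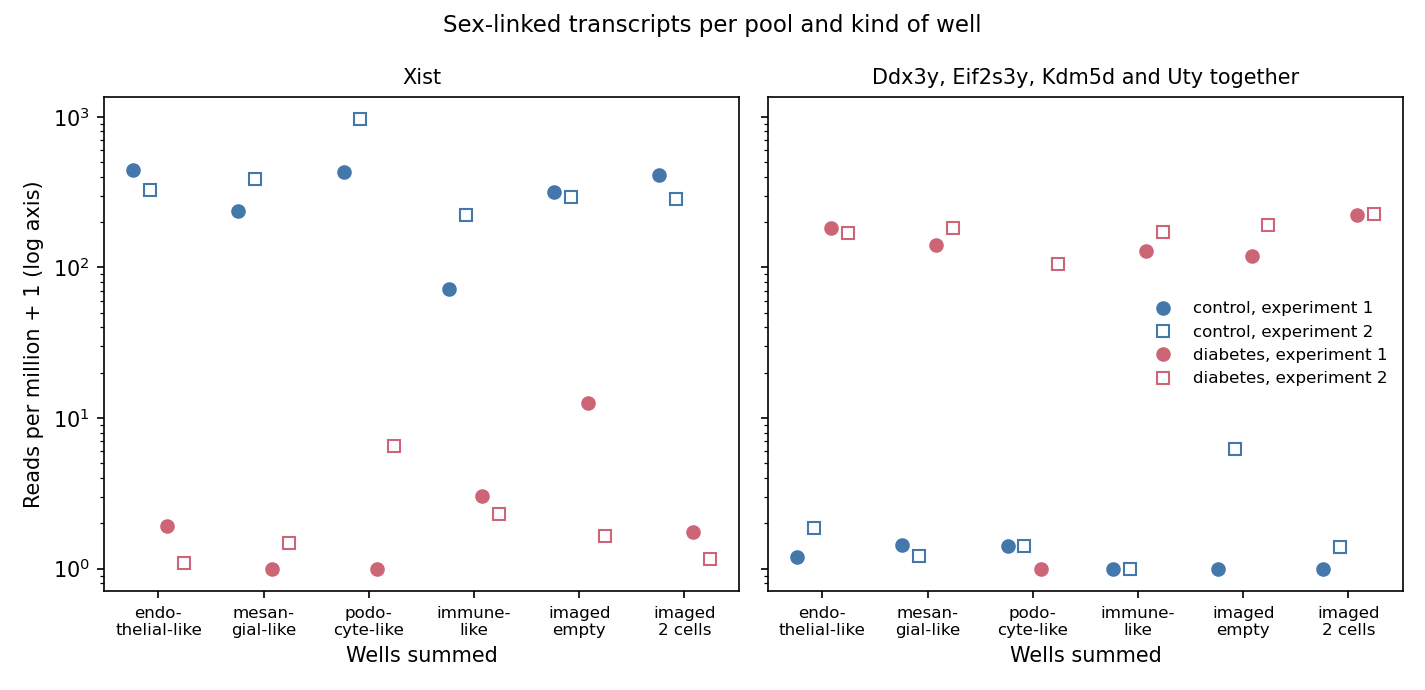
Xist (left) and the sum of 4 Y-linked genes (right) in CPM plus 1, on log axes, for the summed wells of each class and for wells imaged empty or with 2 cells, with 1 point per pool. Over all kept wells the control pools had 356 and 442 CPM of Xist against 1.42 and 1.40 in diabetes; the diabetes pools had 154 and 160 of the Y-linked genes against 0.279 and 0.605.

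Endothelial-like wells, which line the capillaries, were the most numerous class. Xist fell by 10.28 on the log2 scale (SE 0.78, edgeR adjusted p = 0.0452), from 411 and 344 CPM in control to 0.892 and 0.106 in diabetes. It also passed under 13 of 17 alternatives (adjusted p from 1.31e-34 to 1.00). The genes with the next smallest p did not pass and are given as values. Gpihbp1, which carries lipoprotein lipase across capillary endothelium (chromosome 15, 75596628 to 75599481), was at 401 and 1514 CPM in control and 1700 and 6238 in diabetes, a log2 fold change of 2.06 (SE 0.21, adjusted p = 0.152). Lpl, lipoprotein lipase itself, was at 113 and 354 against 913 and 1109 CPM (2.33, SE 0.39, adjusted p = 0.943), and Cd93, an endothelial surface glycoprotein, at 152 and 272 against 500 and 923 (1.74, SE 0.28, adjusted p = 0.943). Hmcn1, an extracellular matrix protein, was at 82.5 and 65.1 CPM in control and 0.595 and 1.12 in diabetes, with 69.8% of a pool's counts from 1 well.

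Among the other genes of smallest p, the Y-linked Ddx3y had 0 and 0.412 CPM in control and 111 and 114 in diabetes. The myeloid gene Lyz2 had 1.59 and 1.49 against 43.1 and 105, and Fxyd6, a regulator of the sodium pump, 113 and 4.43 against 0 and 0. Tmem252 (0 and 26.5 against 15.5 and 384 CPM) had 98.1% of a pool's counts from 1 well. Nos3 had 79.3 and 97.0 CPM in control and 90.1 and 77.3 in diabetes (log2 -0.08, SE 0.48); counts over the whole gene do not check the deletion, whose place in the gene is not given in the sources used here. Most endothelial-like wells of control replicate 2 lay in the cluster led by Emcn, Ly6c1 and Plpp1 (55 of 83). Most of diabetes replicate 2 lay in the one led by Fabp4, Ly6c1 and Gpihbp1 (49 of 93). In experiment 1 the first cluster held 20 of 48 control and 24 of 71 diabetes wells, and the second 8 of 48 and 19 of 71. Values within the class include that difference. Of 12681 genes tested, Xist was the single call, with 532 at an unadjusted p under 0.05 and 1 call without the block. DESeq2 called 89 genes (44 higher, 45 lower), among them Gpihbp1 (adjusted p = 7.90e-11), Lpl (2.42e-06) and Cd93 (0.000191); these were the lowest over all alternatives, and the highest was 1.00 for each. Leaving out control replicate 1 or 2, or diabetes replicate 1 or 2, gave 13, 26, 22 and 15 calls.

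**Figure D3:**
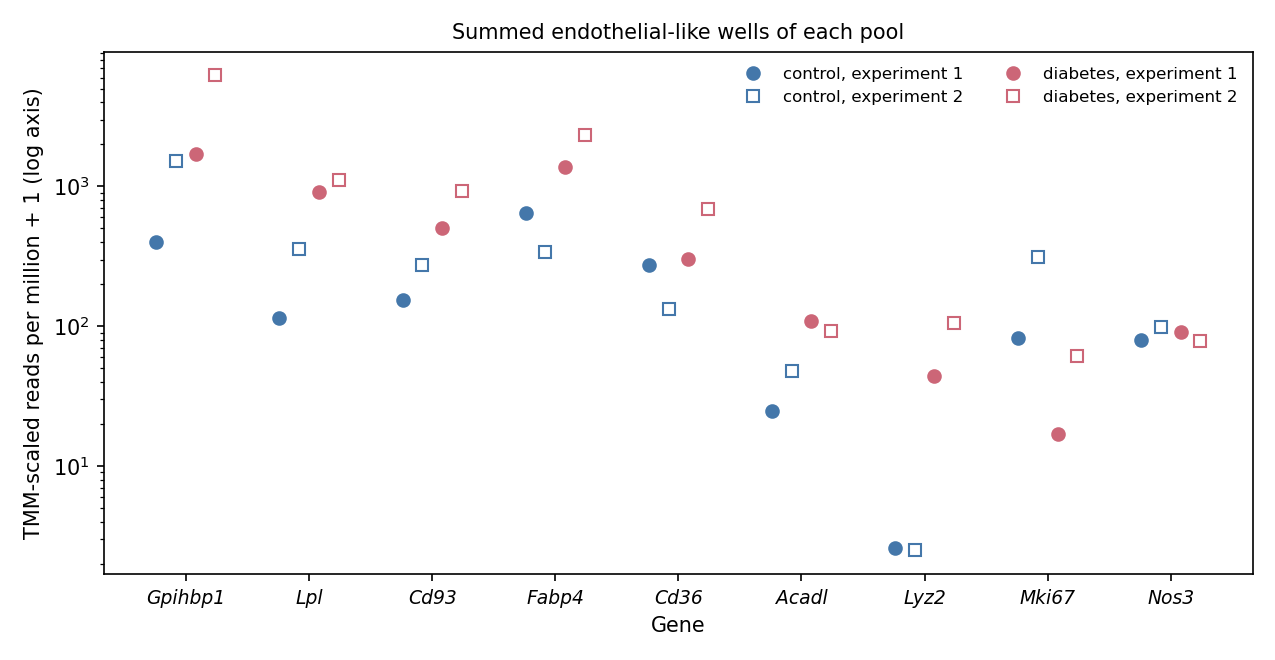
TMM-scaled CPM plus 1 (log axis) of 9 genes in the summed endothelial-like wells of each of the 4 pools. Gpihbp1, Lpl and Cd93 lie higher in the diabetes pool of each experiment, Lyz2 stands at 43.1 and 105 in diabetes against 1.59 and 1.49 in control, and Nos3 lies between 77.3 and 97.0 in every pool.

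By camera, 4 lists passed in endothelial-like wells, and each had an adjusted p = 0.813 with an estimated correlation. That alternative had 1 residual degree of freedom, and its unadjusted p was 0.0972 or more for every list and class, so it does not decide. The immune markers shifted up (adjusted p = 8.45e-05): all 12 measured members had positive fold changes, none passed over all genes and 1 rose when adjusted over the list alone. Fcer1g had 0 and 3.24 CPM in control and 32.1 and 36.5 in diabetes. The complement genes C1qa and C1qc had at most 0.0515 CPM in a control pool and 2.87 to 10.1 in diabetes, with 82.6% of the C1qc counts of a pool from 1 well. The proliferation list shifted down (adjusted p = 0.000132), with 17 of 22 members negative, none past the threshold and 1 lower when adjusted over the list alone. Mki67 had 81.4 and 310 CPM in control and 16.1 and 59.9 in diabetes, and Top2a 109 and 239 against 0 and 74.2, with over 99% of a pool's counts from 1 well. The replication gene Mcm6 went the other way (24.3 and 7.82 against 75.5 and 31.4). The fatty acid oxidation list shifted up (adjusted p = 0.0317), with 10 of 16 members positive, none past the threshold and 1 higher when adjusted over the list alone. The fatty acid carrier Fabp4 had 644 and 341 CPM against 1383 and 2349, and the dehydrogenase Acadl 23.8 and 47.1 against 109 and 91.2. The uncoupling protein Ucp2 had 20.1 and 14.3 against 39.8 and 67.6, and the transporter Cd36 275 and 132 against 304 and 692. The 4 erythroid markers also shifted up (adjusted p = 0.0258), 0 of them past the threshold over all genes or adjusted over the list alone. This rested on 1 well of diabetes replicate 1, which held 99.8% to 99.9% of that pool's reads of each. In experiment 2 the log2 differences were 0.86 for Hbb-bs, -0.09 for Hbb-bt, 0.01 for Hba-a1 and -0.21 for Hba-a2. Without the block the adjusted p was 0.0651 for fatty acid oxidation and 0.408 for the erythroid markers. With thinned wells it was 0.0701 for the immune markers and 0.255 for proliferation. After subtraction of the empty-well profile, an alternative chosen after seeing the data, the immune markers had the opposite direction (adjusted p = 0.664; 3.44e-05 to 0.813 over their alternatives), and the erythroid markers no longer passed (0.137). The mitochondrial genome list passed in that setting alone, shifted up (adjusted p = 0.0133; 0.0685 without the subtraction, and 0.0133 to 0.813 over its alternatives).

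Mesangial-like wells gave 16 called genes of 10415, 10 that rose and 6 that fell. In this fit the p of a typical gene rested on the spread shared across genes and not on its own. The higher count than in endothelial-like wells therefore does not show stronger or better replicated changes. Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590), rose by 2.69 on the log2 scale (SE 0.48, edgeR adjusted p = 9.28e-05), from 105 and 393 CPM in control to 895 and 1916 in diabetes, with 79.1% of the counts of a pool from 1 well. Sncg, gamma-synuclein, rose by 2.29 (SE 0.53, adjusted p = 0.0175; 109 and 302 against 658 and 1204), with 66.1% from 1 well. Both genes are among the leading genes of the smooth muscle or renin cell-like cluster. Genes high in these wells fell as well. The transcription factor Gata3 fell by 2.16 (SE 0.49, adjusted p = 0.0135; 1303 and 1389 against 124 and 713). The secreted Wnt modulator Sfrp2 fell by 1.62 (SE 0.40, adjusted p = 0.0355), and the proteoglycan-cleaving protease Adamts5 fell by 1.45 (SE 0.33, adjusted p = 0.0137; 3623 and 3575 against 1057 and 1641). Steap4, a metalloreductase (chromosome 5, 7960457 to 7982213), fell from 217 and 210 CPM to 0 and 0.180 (adjusted p = 0.000639). The surface sialomucin Cd34 fell by 2.53 (SE 0.63, adjusted p = 0.0426; 534 and 869 against 30.9 and 400). Cd34 is 1 of the 14 endothelial markers, of which 13 were negative in these sums (median log2 fold change -1.14, camera adjusted p = 0.0685, 0.813 with an estimated correlation). Together they had 3778 and 4286 CPM (not TMM-scaled) in control and 2169 and 2667 in diabetes. Xist fell from 225 and 408 CPM to 0 and 0.540 (adjusted p = 7.97e-07).

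A further 7 rises rested on 1 well for over 80% of a pool's counts. Among them were Ggnbp1 (0 and 0 CPM in control, 232 and 35.3 in diabetes) and the retinoic acid enzyme Aldh1a2 (0 and 12 against 155 and 354). Also among them were Fign (30.2 and 16 against 423 and 255), the collagen Col18a1 (84.3 and 29.6 against 482 and 542), the oxidase Cyp1b1 (72.8 and 69.3 against 333 and 883) and Igfbp5, a binder of insulin-like growth factors (5029 and 4494 against 12928 and 6968). The complement gene C3, singled out after its values were seen, was also called (adjusted p = 0.000344), with 0 CPM in both pools of experiment 1 and 7.14 against 955 in experiment 2. These sums came from 29 and 68 control wells and 5 and 23 diabetes wells. At an unadjusted p under 0.05 there were 280 genes, and DESeq2 called 26, of which 8 were among the 16. Without the block 1 gene (Xist) was called. The fits that leave out a pool also drop the block, so their counts do not show the effect of that pool alone. Leaving out control replicate 1 or 2, or diabetes replicate 1 or 2, gave 1, 5, 42 and 19 calls, of which 1, 2, 9 and 2 were among the 16. The median log2 fold change of all genes was -0.41 (-0.36 with RLE scaling). It was -0.83 in experiment 1, which had 5 diabetes wells, and -0.03 in experiment 2, so no common shift holds in both. Relative to the median gene of experiment 1 the rises named here are larger and the falls smaller, and in experiment 2 hardly so.

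**Figure D4:**
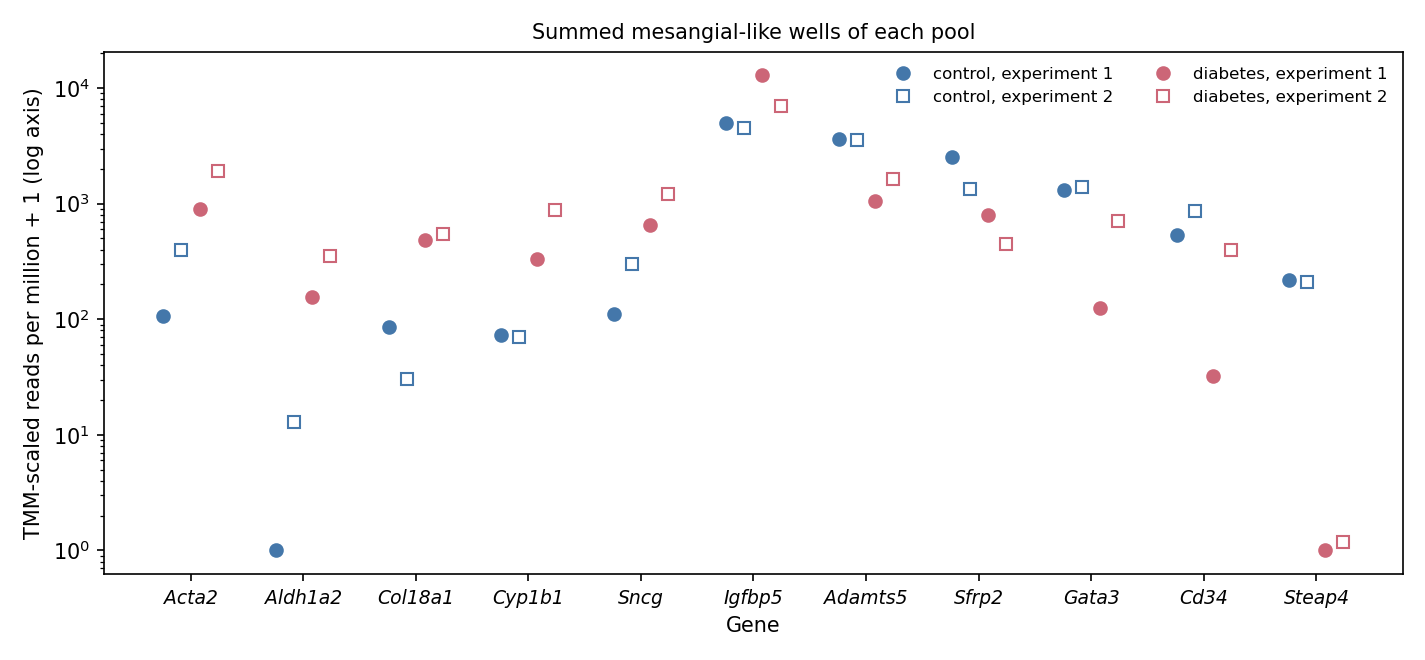
TMM-scaled CPM plus 1 (log axis) of 11 called genes in the summed mesangial-like wells of the 4 pools. The wells behind each point number 29 and 68 in control and 5 and 23 in diabetes; Acta2 and Sncg lie higher, and Adamts5, Sfrp2, Gata3, Cd34 and Steap4 lower, in the diabetes pool of each experiment.

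By camera, 7 lists passed in mesangial-like wells. Each had an adjusted p = 0.813 with an estimated correlation, which does not decide here either. The contractile apparatus shifted up (adjusted p = 1.44e-05): 15 of 18 members were positive and 1, Acta2, rose, also when adjusted over the list alone. The smooth muscle and renin cell markers shifted up (adjusted p = 8.43e-05), with 5 of 6 positive, 1 that rose and 2 adjusted over the list alone. As fixed, this list shares Acta2, Tagln, Cnn1, Myh11 and Mylk with the contractile list, so the 2 shifts are not separate results. Acta2 had reads in 20.7% and 55.9% of control and 60% and 65.2% of diabetes wells, and Rgs5 in 34.5% and 14.7% against 60% and 65.2%. The wells with most of these markers held 53.4% (1 of 5 wells) and 53.4% (2 of 23) of their reads in diabetes and 31.4% (2 of 29) and 34.4% (4 of 68) in control. For the mesangial markers 1 of 5 wells of diabetes replicate 1 held 52.2%. Rgs5, a pericyte regulator of G proteins, had 298 and 39.2 CPM against 841 and 221. Myh11, smooth muscle myosin, had 0 and 0.140 against 30.9 and 18, the 30.9 from 1 of 5 wells and the 18 from 26.1% of the wells of its pool. The myosin kinase Mylk had a log2 fold change of -0.46 (SE 0.40). Tpm1 and Tpm2, tropomyosins, were at 381 and 548 against 838 and 849, and 253 and 556 against 750 and 682. The cytosolic ribosome shifted up (adjusted p = 1.93e-10), with 64 of 80 proteins positive and 0 past the threshold, over all genes or adjusted over the list alone. Rps12 had 260 and 424 CPM against 1024 and 706, and Rpl13 404 and 397 against 887 and 739. The oxidative stress list shifted up as well (adjusted p = 8.43e-05; 17 of 23 positive, 0 past the threshold over all genes or adjusted over the list alone). The ferritin chain Fth1 had 1776 and 1950 CPM against 2746 and 4289, and Ftl1 193 and 217 against 536 and 391. Further members were the peroxiredoxin Prdx1 (1667 and 778 against 1681 and 1594) and the glutathione peroxidase Gpx1 (192 and 331 against 353 and 544).

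The extracellular matrix list shifted up (adjusted p = 0.00265), with 22 of 32 members positive; Col18a1 rose over all genes, and 3 rose and 1 fell when adjusted over the list alone. Igfbp7 had 8152 and 8234 CPM against 15540 and 11861. Fibronectin (Fn1) had 0 and 4.62 against 676 and 17.4, and periostin (Postn) 124 and 19.1 against 0 and 0, with 99.8% and 99.6% of a pool's counts from 1 well. Antigen presentation shifted up (adjusted p = 0.0257; 10 of 17 positive, 0 past the threshold over all genes or adjusted over the list alone). B2m, the class I light chain, was at 1486 and 2912 CPM against 1978 and 4970, and H2-Q4 in the other direction at 55.0 and 163 against 5.16 and 63.3. Cholesterol and fatty acid synthesis shifted down (adjusted p = 0.0257), with 1 of 16 members positive and 0 past the threshold over all genes or adjusted over the list alone. Sqle had 201 and 71.9 CPM against 0 and 9.53, and Fasn 39.9 and 56.7 against 2.58 and 1.98. Of the 12 mesangial markers, Gata3 and Sfrp2 fell and 4 fell when adjusted over the list alone, but the list as a whole did not pass (adjusted p = 0.319). With thinned wells it passed, shifted down (adjusted p = 0.00624; 0.00624 to 0.813 over its alternatives). Without the block the adjusted p was 0.17 for antigen presentation and 0.139 for cholesterol and fatty acid synthesis. With thinned wells 5 lists no longer passed: contractile apparatus (adjusted p = 0.255), smooth muscle and renin cell markers (0.0540), extracellular matrix (0.0822), antigen presentation (0.560) and cholesterol and fatty acid synthesis (0.583). After subtraction of the empty-well profile, chosen after seeing the data, the last 2 had 0.0982 and 0.0839. Nos3 had 8.87 and 14 CPM in control and 2.58 and 60.4 in diabetes, the 2.58 from 1 of 5 wells.

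In immune-like wells 4 of 8326 genes were called, and most alternatives ended the call of Apoe. As in mesangial-like sums, the p of a typical gene rested on the shared spread and not on its own. Apoe, the lipid carrier that macrophages make (chromosome 7, 19696109 to 19699188), rose by 4.12 on the log2 scale (SE 0.91, edgeR adjusted p = 0.0138), from 1159 and 26.5 CPM in control to 4269 and 2279 in diabetes, with 73.0% of the counts of a pool from 1 well. The immunoglobulin light chains Igkc (0 and 67.6 against 90.6 and 41856 CPM, adjusted p = 7.36e-28) and Iglc2 (0 and 0 against 11.9 and 1439, adjusted p = 0.00735) rose as well, with 93.7% and 96.0% of a pool's counts from 1 well. Apoe passed under 6 of 18 alternatives, Igkc under 12 of 18 and Iglc2 under 9 of 17. The fourth call was a fall of a predicted gene model. Genes of next smallest p, which did not pass, were Axl, a receptor for apoptotic cells (184 and 38.4 against 1406 and 499 CPM), and the macrophage genes C1qc (1285 and 0 against 2368 and 415) and Ms4a7 (471 and 0 against 1452 and 347). Others were Sec11c (0 and 2.65 against 152 and 560), H2-DMa (1939 and 1287 against 859 and 24.9), Egr1 (1320 and 725 against 121 and 86.9) and C1galt1c1 (493 and 103 against 5.22 and 0.429). Of these, C1qc, H2-DMa, Egr1 and C1galt1c1 had 81.1%, 99.8%, 99.6% and 87.2% of the counts of a pool from 1 well.

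Markers of cell types differed between these sums as well (CPM not TMM-scaled). The immune markers had 27213 and 9438 CPM in control and 32640 and 9404 in diabetes, the endothelial markers 705 and 7526 against 1127 and 3625, and the erythroid markers 0 and 0 against 2.53 and 21373, with 99.9% of the last in 3 wells. The control sums rest on 5 wells each, and the median log2 fold change of all genes was 1.02 (0.76 with RLE scaling). It was 1.55 in experiment 1 and 0.87 in experiment 2, so changes are relative to a shift that differs by experiment. At an unadjusted p under 0.05 there were 201 genes. DESeq2 called 3 and the fit without the block 0, and the fits leaving out a pool drop the block as well. Leaving out control replicate 1 or 2, or diabetes replicate 1 or 2, gave 556, 164, 11 and 0 calls. Without the 4 immune-like wells with over 1% immunoglobulin reads, a setting added after seeing the data, 2 genes were called: Apoe still passed (its adjusted p ran from 2.24e-06 to 1.00 over all alternatives), while Igkc and Iglc2 no longer did. By camera 4 lists passed, each with 0 members past the threshold, over all genes or adjusted over the list alone. Each had an adjusted p = 0.813 with an estimated correlation, which does not decide here either. The immediate-early and dissociation list shifted down (adjusted p = 3.01e-07, 6 of 27 positive), with Nr4a1 at 585 and 500 CPM against 12.8 and 94.6 and the heat shock gene Hspa1a at 3144 and 3829 against 1265 and 2846. The cytosolic ribosome shifted down (adjusted p = 6.73e-06, 31 of 80 positive; Rpl7 1073 and 3144 against 806 and 977, Rpl10 367 and 939 against 1286 and 1555). Proliferation shifted up (adjusted p = 0.00545, 9 of 10 positive), with Mki67 at 0 and 0 CPM against 226 and 42.5 and Tyms at 0 and 2.65 against 209 and 61.3. The endothelial markers shifted down (adjusted p = 0.00359), although their median log2 fold change was 0.12 and their mean -0.05; Kdr had 115 and 1763 CPM against 95.8 and 714, with 90.0% of the counts of a pool from 1 well. After subtraction of the empty-well profile, chosen after seeing the data, the ribosome had an adjusted p = 0.178. The mitochondrial genome list then passed, shifted up (adjusted p = 1.22e-05; 0.242 without the subtraction, and 1.22e-05 to 0.961 over its alternatives). Without the block the adjusted p was 0.139 for proliferation and 0.0990 for the endothelial markers. With thinned wells it was 0.235 and 0.824, the latter with the opposite direction.

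Podocyte-like wells numbered 24 and 31 in control but 2 and 19 in diabetes, so diabetes replicate 1 gives values only. The slit diaphragm gene Nphs1 (nephrin) had 1489 and 1743 CPM in control. Diabetes replicate 2 had 854, and the 2 wells of diabetes replicate 1 had 227. Of 14 podocyte markers, 7 were lower in diabetes replicate 2 than in both control pools and 2 were higher. Of 21 slit diaphragm and foot process genes 9 were lower and 4 higher, among them Col4a3, a collagen of the glomerular basement membrane (580 and 1043 against 2342). No member of either list passed in a fit of 3 pools without the block, in which the lone diabetes pool is assumed to vary like the control pools and which was added after seeing the data. The median log2 fold change of all genes in that fit was -0.31, against -0.42 for the podocyte markers and -0.16 for the slit diaphragm list. That fit called 20 of 11470 genes, 15 higher and 5 lower, with 767 at an unadjusted p under 0.05. With all 4 pools the fit with the block called 0 genes in edgeR (207 at an unadjusted p under 0.05) and the fit without it 1, and DESeq2 called 175 in the 3 pools.

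Among those 20, all chosen after their values were seen, Gpihbp1 stood at 14.5 and 113 CPM in control and 2292 in diabetes replicate 2 (log2 5.21, SE 0.79, edgeR adjusted p = 6.98e-07), and Xist at 432 and 1298 against 7.01. The retinoic acid hydroxylase Cyp26b1 had 0 and 2.91 CPM against 329, Stmn2 0 and 16.9 against 295, Cyp1b1 0 and 5.82 against 218, and Pcsk6, a proprotein convertase, 267 and 351 against 0.877. Diabetes replicate 1, outside that fit, had 0 CPM of Cyp26b1, Stmn2, Cyp1b1 and Xist in its 2 wells. Those wells had 40.1 CPM of Pcsk6 and 294 of Gpihbp1. Markers of other cells moved with them: the endothelial markers together had 882 and 3958 CPM (not TMM-scaled) in control and 5563 in diabetes replicate 2, and the immune markers 12.9 and 24.8 against 642.

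The response to diabetes was not found to differ between endothelial-like and mesangial-like wells for any of 12983 genes by edgeR (0 calls, 432 at an unadjusted p under 0.05); DESeq2 called 16, and edgeR without a gene filter 2. The genes called in mesangial-like wells alone are therefore not shown to respond differently from endothelial-like wells. Using all 4 pools, an alternative added after seeing the data because 1 pool held 2 podocyte-like wells, edgeR called 0 genes for endothelial-like against podocyte-like wells (483 at an unadjusted p under 0.05) and 0 for mesangial-like against podocyte-like wells (419). DESeq2 was not run on these.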

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

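In this part, all tests but the 2 on immune-like wells named from free RNA were chosen after the results were seen, and so was the condition on mesangial-like wells in the test of free RNA in endothelial-like sums. Wells outside the comparisons of the report, those imaged empty, with 2 cells, or with more than 2 cells or debris, held signals above their level in the control pools. In wells imaged empty the immune markers stood at 4714 CPM (experiment 1) and 1733 CPM (experiment 2) in diabetes against 503 and 143 in control, and the erythroid markers at 1642 and 279 against 1.32 and 43.9. The 4 Y-linked genes had 118 and 190 CPM in the empty wells of the diabetes pools against 0 and 5.20 in control. They had 221 and 226 in wells with 2 cells against 0 and 0.389, and 563 and 242 in wells with more than 2 cells or debris against 0 and 0.291.

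The first pattern weighed was Xist in the control pools and Y-linked reads in the diabetes pools. An effect of diabetes in mice of 1 sex is argued against by the Y-linked reads of the control pools, which over all kept wells were 0.379% or less of those in diabetes in each experiment. In smaller sets of wells the share reached 2.73% (wells imaged empty) and 17.1% (6 control and 3 diabetes tubular-like wells) in experiment 2, and the 2 podocyte-like wells of diabetes replicate 1 held no such reads. A pool with 1 of 3 mice of the other sex would have about 0.33 of its wells with reads of the other kind alone, if mice gave equal numbers of cells. The largest upper 95% limit of that share was 13.1%. Control pools of female mice and diabetes pools of male mice remain a candidate explanation, with at most 3.13% of the wells of a pool holding only reads of the other kind. That would differ from the sex-matched littermates of the design text, and whether the text, the labels or the mice differ is not settled by these data.

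The second pattern was the higher share of immune-like wells in diabetes. The filters on wells are argued against, since without any filter the smaller of the 2 differences was 17 percentage points. A stricter limit of 15% mitochondrial reads left 13 of the 41 immune-like wells of diabetes replicate 2 and a difference of 10.1 there, so wells with more mitochondrial reads held part of it. A mere loss of mesangial-like and podocyte-like wells is argued against in experiment 1 by the odds ratio of immune-like to endothelial-like wells. It was 3.76 (95% limits 1.31 to 13.3), counting error only, with 1 pool against 1. There 5 of 5 control and 22 of 28 diabetes immune-like wells exceeded the 95th percentile of the empty wells. In experiment 2 the odds ratio was 7.26 (2.69 to 24.7), but 3 of 5 control and 10 of 41 diabetes wells exceeded that limit. It counts wells whose naming is in doubt and does not decide there. Wells named from free RNA are argued against in experiment 1, where 78.6% of immune-like wells of the diabetes pool exceeded the 95th percentile of its empty wells. They may account for part of experiment 2, where 24.4% did. Empty wells in which a cell was missed would lower both values. The empty-well profile would give 4.07% of the immune marker reads of the immune-like wells of diabetes replicate 2. Free RNA at that level is argued against as the source of most of these reads, of which 3 wells held 46.8%. Their median immune marker share was 0.262%, against 0.0473% in empty wells of that pool. Diabetes, sex and the digestion of each pool stay open and could not be separated.

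The third pattern was the immune markers in endothelial-like sums of the diabetes pools. The empty-well profile of the same pool would give 82.5% and 129% of those reads, which met the criterion as first set, before mesangial-like wells were looked at. It would also give 239% and 498% of the immune marker reads of mesangial-like sums, more than were there, so it overstates free RNA and does not decide. Wells that also held an immune cell are a further possible explanation: the 5% of wells with most such reads held at most 50.8% of them, which neither requires nor excludes it. Free RNA, wells with a second cell, and immune transcripts made by the endothelium cannot be told apart here, because no measure of free RNA apart from the empty wells was at hand.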

How the results depend on the processing

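In this part, the tests with the empty-well profile subtracted, without chromosomes X and Y, without immunoglobulin-rich wells, with no filter on wells, and all podocyte-like tests were chosen after the results were seen. The cause of a change was not tested unless stated. Called genes in endothelial-like wells (1) were 89 with DESeq2, 9 with the mean of log values, 8 with every gene, 5 with thinned wells, 4 with classes from the highest marker share, and 13 to 26 leaving out 1 pool. They were 0 by edgeR with the empty-well profile subtracted, at least 1000 genes per well, no mixed wells, RLE factors, or without chromosomes X and Y, which removes Xist (260, 488, 522, 521 and 506 at an unadjusted p under 0.05). In mesangial-like wells (16) they were 26 with DESeq2, 2 with mean log values, 3 with thinned wells (4569 genes tested), 1 without the replicate block and 1 to 42 leaving out 1 pool. In immune-like wells (4) they were 14 with every gene, 2 with the profile subtracted, with mitochondrial reads at most 15%, without mixed wells or without immunoglobulin-rich wells, and 1 by highest marker share. They were 0 by limma on mean log values (749 at an unadjusted p under 0.05) and without the block by edgeR (940), and 0 to 556 leaving out 1 pool. In 3 podocyte-like pools (20) they were 175 with DESeq2, 49 at 15% mitochondrial reads, 34 by marker share and with thinned wells, 12 with library size, 7 with every gene, 5 with a stricter filter, and 4 with the profile subtracted. With all 4 pools they were 1 without and 0 with the block (386 and 207 at an unadjusted p under 0.05). The difference between endothelial-like and mesangial-like wells (0) gave 16 with DESeq2 and 2 with every gene.

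Of the 15 lists that passed, 0 passed with an estimated correlation or by fry. Both alternatives rest on 1 residual degree of freedom. Over the 84 tests the smallest unadjusted p was 0.0972 by camera with an estimated correlation and 0.00298 by fry. They could hardly pass after adjustment and do not decide, so the shifts rest on the preset correlation. Over all lists 9 passed without the block and 7 with thinned wells. The fit without the block changed no other count of calls by over 1.5 times. Values that reversed were mesangial-like Igfbp5 with mean log values (-0.24), the immune list in endothelial-like wells with the profile subtracted (adjusted p = 0.664) and the endothelial list in immune-like wells with thinned wells (0.824). Named genes kept direction and side of the threshold in 408 endothelial-like, 444 immune-like and 581 mesangial-like comparisons with an alternative. With direction kept, they lost the threshold in 4, 26 and 126 and gained it in 46, 14 and 8. Genes that passed in neither fit count as kept. Comparisons within 1 experiment have no threshold and count as kept if the change moved by under 1 SE. Of the 15 mesangial-like genes called and named by the rule, 14 lost the threshold without the block, 8 with DESeq2 and 1 with RLE factors. Mean share differences were 17.7 (highest marker share) and 6.15 (no filter) points for endothelial-like, -18.3 (15% mitochondrial reads), -18.4 (marker share) and -15.5 (no filter) for mesangial-like wells. They were 14.8, 13.1 and 9.79 (15% mitochondrial reads, marker share, resolution 1.2) for immune-like wells. Genes per single-cell well over empty well, as a mean of the control and diabetes ratios, were 6.17 and 1.16 in experiments 1 and 2. These count genes with at least 2 counts. Some alternatives left under 5 wells in a pool of mesangial-like or immune-like wells and were still fitted. Leave-outs assume that the lone pool varies like the other condition. They also drop the block, so their counts do not show the effect of the pool left out alone. The podocyte-like tests as planned were not run, since 1 pool held 2 wells.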

Other observations

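No test was chosen after a result was seen in this part, which gives values without a test. Immunoglobulin reads exceeded 1% of a well's reads in 8 kept wells, all in diabetes replicate 2, and 4 of them were immune-like. Erythroid reads came from few wells: 1 well of diabetes replicate 1 with 41.5% erythroid reads held 99.6% of that pool's. The 2 richest wells of diabetes replicate 2, up to 67.2%, held 98.2%. Without these wells the pools had 26 and 63.5 CPM instead of 6452 and 3502. Smooth muscle or renin cell-like wells were 5.00% and 3.45% of control and 3.13% and 1.60% of diabetes wells. Tubular-like wells were 4.17% and 2.96% against 7.81% and 1.60%, and the unnamed wells led by Mgp, Col1a2 and Dcn 2.50% and 1.48% against 6.25% and 3.19%.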
